A study of Mus musculus with 12 samples.

How the data were processed

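RNA from 12 cultures of MMT cells, a line from a mouse mammary tumour, was measured on single-colour Applied Biosystems arrays with a digoxigenin label and chemiluminescent detection, after amplification by reverse transcription and in vitro transcription, per the labels. The 4 groups were untransfected cells (2 arrays) and cells transfected with a control siRNA (siCtrl, 3 arrays), an siRNA against Erm (siErm, 3 arrays) or an siRNA against Pea3 (siPea3, 4 arrays), and per the labels the replicates are biological. Groups were taken from the sample titles. The deposited intensity of each probe is an assay normalized signal on a linear scale, per the file headers. The coefficient of variation deposited beside it is a ratio, per the file headers, and was read as noise over signal of the same measurement. A status code per measurement marks failed measurements. The software, the background correction and any scaling between arrays are not given in the sources used here.

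The deposited intensities of the series table were checked against those of the separate arrays. All 392662 filled values were equal, and the 3482 blanks were measurements with a failed status. Of the measurements with a coefficient of variation over 1, 99.97% carried the mark for low signal, so the inverse of the coefficient was taken as the signal-to-noise ratio. No pair of arrays shared more than 0.754% of identical values.

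Intensities were kept as deposited and taken to log2, and failed measurements (145 to 438 per array) were left out. A probe was called detected on an array at a signal-to-noise ratio of at least 3, and was kept if detected on at least 2 arrays. This kept 16726 probes, and 16724 had values in every group and were tested. Probes were matched to genes through the annotation table supplied for the array. It gives 1 gene symbol for 14411 probes, several for 247 and none for 18354, and 9182 of the tested probes (54.9%) had 1 symbol. Symbols of 14402 probes were looked up by gene identifier in a RefSeq table and 0 were renamed. No genome build is named, so no positions are given.

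Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group, all 12 arrays, no covariates, 8 residual and 3.06 prior degrees of freedom). P values were adjusted by the Benjamini-Hochberg method over the tested probes, and a probe was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from that fit, and errors of signals are standard deviations. The comparisons were siPea3 with siCtrl, siErm with siCtrl, siCtrl with untransfected cells, and siPea3 with siErm. Where a probe was not detected on any array of 1 group, its fold is written with "at least". It was taken from the mean of the brighter group and, on each array of the other, the higher of its signal and the lowest signal of any detected probe. Undetected signals can lie above that lowest signal, so this allows for background only in part, and not for the spread between arrays. Such a fold is therefore an estimate and not a strict lower bound. It equals the fitted fold where the undetected signal was the higher. Log2 changes are fitted estimates and not bounds, also for such probes. Single probes for the targeted genes were also compared by exact permutation of the array labels, 2-sided and without regard to replicate numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

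Gene lists (34, with 654 distinct genes, of which 420 had a tested probe) for pathways, stress responses and cell types, and the ribosomal protein genes as another list, were tested with camera in limma at a preset correlation of 0.01, with 1 probe per gene (the one with the highest mean over all arrays). These p values were adjusted over 35 lists and 4 comparisons, 140 tests. Camera was also run with a correlation estimated from the residuals, and fry was run, which tests whether a list's genes move on balance one way and does not compare them with other genes. List medians are given relative to the median of all tested probes in the same comparison where stated. Members of a list were also adjusted over the list alone. That adjustment does not cover the other lists or comparisons, so a gene passing only there is weaker evidence than 1 passing over all probes. The lists, the comparisons, the filter, the tests, the rule below and most alternatives were fixed before the data were examined.

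Genes were named by a rule. Etv4, Etv5 and Etv1 are always given. In each comparison the 10 largest rises and the 10 largest falls are named among called probes with 1 symbol whose groups of arrays did not overlap. Where fewer than 5 passed in a direction, those with the smallest p are added up to 5 and said not to pass. For each list up to 4 members with the smallest p may be named. Probes with several symbols or none are counted, with exceptions that are said to have been chosen after their values were seen.

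The tests were tried on simulated data in which 100 probes changed by 1 and 100 by 2 on the log2 scale among the 16724 probes. The smaller change was called for 6% of probes in siPea3 with siCtrl, 3% in siErm with siCtrl, 2% in siCtrl with untransfected cells and 6% in siPea3 with siErm. The larger change was called for 56%, 46%, 35% and 54% in the same order, with 4, 0, 6 and 4 unchanged probes called. Of 6 list tests with a log2 shift of 1, 6 were called, and of 134 without a shift, 2 were called. The simulated probes varied independently of each other. In the data the estimated correlation was 0.808 for cholesterol synthesis genes and 0.42 for p53 targets. The share of lists called without a shift therefore does not carry over to the list calls below.

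Whether equal replicate numbers pair the arrays was checked on residual correlations. Between siCtrl and siErm, arrays of 1 number correlated at 0.268, 0.308 and 0.22, against at most -0.116, -0.0811 and 0.0523 for other numbers. The numbers therefore appear to pair these arrays. Between siCtrl and siPea3 the values were 0.109, 0.316 and 0.158, against at most 0.0867, 0.0466 and 0.307, so pairing is uncertain there. Between siErm and siPea3 they were -0.0425, 0.033 and 0.073, each below that of another number. Between untransfected and siCtrl arrays they were 0.0803 and 0.0665, against at most 0.00885 and -0.00882. These are too small to settle pairing. A fit with the replicate number as a block was run as an alternative. Other alternatives were quantile normalization, median scaling over all probes or over probes detected on all arrays, the series table, no filter and a stricter filter, an intensity trend with a robust prior, fits of only the groups compared, array weights, failed measurements kept, leaving out each array in turn, and leaving out siPea3 array 2 and siCtrl array 2 together. The median scalings, the failed measurements, the last pair of arrays, the block within only the groups compared and the left-out arrays for lists were added after the data were examined.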

Results

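The arrays measured gene expression in MMT cells without transfection (2 arrays), with a control siRNA (siCtrl, 3 arrays), with an siRNA against Erm (siErm, 3 arrays) and with an siRNA against Pea3 (siPea3, 4 arrays). Erm and Pea3 are older names of Etv5 and Etv4, which together with Etv1 (Er81) form the PEA3 group of ETS transcription factors. Between 11286 probes (34.2%, siPea3 array 2) and 13836 (41.9%, untransfected array 1) were detected per array. The upper quartile of signal was 7.47 on siPea3 array 2 and 10.2 to 14.4 on the other arrays. Log2 signals correlated across probes, which are not independent replicates, at r = 0.939 to 0.973 within groups and 0.888 to 0.976 between groups. The small number of arrays limits the precision of every comparison.

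The targeted genes check the knockdowns. Etv4 signal was 19.0 ± 2.17 (SD, n = 4) in siPea3 cells, 36.9 ± 5.89 (n = 3) in siCtrl cells, 34.9 ± 9.77 (n = 3) in siErm cells and 41.3 ± 0.75 (n = 2) in untransfected cells. The siPea3 arrays lay at 16.4 to 21.1 and the siCtrl arrays at 31.5 to 43.2, a log2 change of -0.95 ± 0.24, or 1.93-fold lower. An exact permutation test on this probe gave p = 0.0286, 2-sided, the smallest that 35 splits allow. It treats the arrays as unpaired. If the replicate numbers pair them, the splits left are too few for a p under 0.05. In the limma fit Etv4 did not pass over all probes (adjusted p = 0.195, 0.0624 to 0.514 over 20 alternatives) and fell adjusted over the list alone, that is over Etv1, Etv4 and Etv5 (adjusted p = 0.00714). That list was not called by camera (adjusted p = 0.129). Against siErm cells, Etv4 in siPea3 cells differed by -0.85 ± 0.24 on the log2 scale (adjusted p = 0.34 over all probes, 0.0151 adjusted over the list alone). Between siErm and siCtrl cells Etv4 differed by -0.10 ± 0.26 (adjusted p = 1, exact permutation p = 0.8), and the sign of this estimate turned without siCtrl array 2 (0.016) or siErm array 1 (0.072).

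Etv5 was close to background on these arrays, so its probe does not check the Erm knockdown. It was detected on siCtrl arrays 1 and 2 and on untransfected array 1 and on no siErm or siPea3 array. Mean signal was 0.94 ± 0.719 (n = 3) in siErm cells and 1.64 ± 0.982 (n = 3) in siCtrl cells (log2 -0.90 ± 0.93, adjusted p = 1, exact permutation p = 0.3, where 0.1 is the smallest possible). By replicate number, Etv5 signal was 1.77, 0.54 and 0.51 on siErm arrays and 2.77, 1.16 and 0.99 on siCtrl arrays. It was lower on the siErm array each time, but near background. In siPea3 cells mean signal was 0.712 ± 0.105 (n = 4). The log2 difference was -1.06 ± 0.87 from siCtrl cells (adjusted p = 0.593) and -0.16 ± 0.87 from siErm cells (adjusted p = 0.958). The sign of the last turned without siErm array 1 (0.43). In untransfected cells it was 12.4 ± 16 (n = 2), from 23.7 on array 1 and 1.05 on array 2. The adjusted p of siCtrl against untransfected cells was 0.545, but 0.0269 without untransfected array 2 (0.0269 to 0.951 over 16 alternatives). The estimate turned from -1.76 to 0.49 without untransfected array 1. Etv1 was 5.23 ± 5.24 (n = 4) in siPea3, 7.29 ± 3.35 (n = 3) in siErm, 11.4 ± 4.43 (n = 3) in siCtrl and 10.2 ± 0.184 (n = 2) in untransfected cells. Its log2 difference from siCtrl was -1.61 ± 0.70 in siPea3 cells (adjusted p = 0.356, exact permutation p = 0.114; -2.23 without siPea3 array 1) and -0.68 ± 0.75 in siErm cells (adjusted p = 1, exact permutation p = 0.3). By replicate number, Etv1 signal was 7.74, 10.4 and 3.74 on siErm arrays and 13.22, 14.65 and 6.36 on siCtrl arrays. Etv1 was thus lower on the siErm array each time, and was detected on all of these arrays. The limma and permutation tests of Etv1 treat the arrays as unpaired, although the numbers appear to pair them, so they can miss such a fall. Between siPea3 and siErm cells the log2 difference of Etv1 was -0.93 ± 0.70 (adjusted p = 0.643, and -1.55 without siPea3 array 1). Between siCtrl and untransfected cells Etv4 differed by -0.17 ± 0.29 (adjusted p = 0.846) and Etv1 by 0.072 ± 0.84 (adjusted p = 0.981), which turned without siCtrl array 2 (-0.15).

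**Figure D1:**
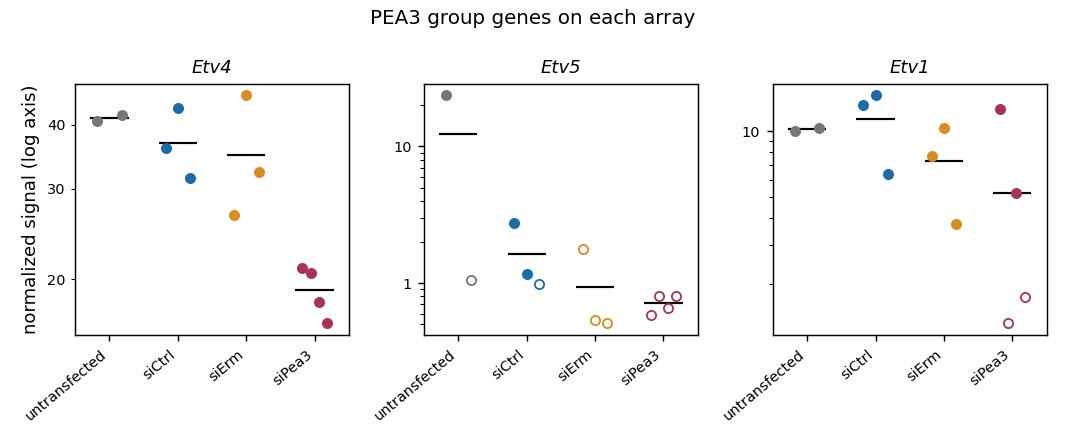
Normalized signal (log axis) of Etv4, Etv5 and Etv1 on each of the 12 arrays, by group; filled points were detected, open points were not, and bars are group means. Etv4 lies between 16.4 and 21.1 on the 4 siPea3 arrays, below every array of the other groups, and Etv5 is undetected on the 3 siErm and 4 siPea3 arrays.

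The comparison of siCtrl with untransfected cells shows what the transfection protocol changes, the purpose the design text gives for the untransfected cells. Interferon and chemokine genes were among the largest rises named. Ccl5, a chemokine that attracts T cells, rose from 194 ± 49 (n = 2) to 3150 ± 471 (n = 3), a log2 rise of 4.04 ± 0.49 (adjusted p = 0.0032), and Ccl4, a related chemokine, rose from 28 ± 26.7 to 344 ± 75.1. Ifnb1, the gene of interferon beta, rose from 10.7 ± 7.24 to 202 ± 31.8 (log2 4.42 ± 0.78, adjusted p = 0.0252), and Ifna4, an interferon alpha gene, rose from 1.78 ± 1.63 to 21.6 ± 8.89. The Ifna genes are so alike that a probe can read several. Il6, the gene of interleukin 6, rose 12.7-fold, from 25.5 ± 18.5 to 301 ± 154 (adjusted p = 0.0101). Without untransfected array 2 and without untransfected array 1, the log2 rise was 2.85 and 5.21 for Ccl4, 3.67 and 5.17 for Ifnb1, 2.78 and 5.02 for Ifna4, and 2.85 and 4.48 for Il6.

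Genes of stratified epithelium were also among the largest rises. Sprr1b, a precursor of the cornified envelope, went from 6.25 ± 6.66 (n = 2) to 124 ± 63.1 (n = 3), and Ivl (involucrin, another such precursor) from 0.775 ± 0.445 to 14.8 ± 7.23. Zfp750, a transcription factor of epidermal differentiation, was at least 24.8-fold higher (11 ± 4.05 against an undetected 0.365, adjusted p = 0.00073). The other named rises were Prl8a9, a prolactin family gene (1.24 ± 0.884 to 59.4 ± 60.1), Slc2a6, a glucose transporter gene (5.06 ± 1.87 to 78.5 ± 20.5, adjusted p = 0.00142), and Rgcc, a regulator of cell cycle (at least 20.5-fold). Without untransfected arrays 1 and 2 in turn, the log2 rise was 3.36 and 6.19 for Sprr1b, 4.88 and 3.63 for Ivl, and 4.49 and 6.10 for Prl8a9, which was 5.91 and 4.49 without siCtrl arrays 1 and 2. For Rgcc it was 3.63 and 5.22 without siCtrl arrays 1 and 2.

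Fewer probes fell than rose, 20 against 151, though without untransfected array 2 it was 148 against 188. Lbh, a transcriptional cofactor, fell from 167 ± 72.7 (n = 2) to 27.5 ± 7.63 (n = 3), Dll4, a Notch ligand, from 24 ± 4 to 3.33 ± 0.611, Prmt1, a protein arginine methyltransferase, from 598 ± 201 to 156 ± 25.6, and Efnb1, the ligand ephrin B1, from 86 ± 24.8 to 26.6 ± 4.29. Genes that fell to undetected levels were the olfactory receptor Olfr1101 (at least 10-fold), Sele, the endothelial adhesion molecule E-selectin (at least 5.19-fold), Spata32 (at least 5.15-fold), Sdr16c5, a retinol dehydrogenase (at least 4.83-fold), Ptgfr, the prostaglandin F receptor (at least 3.54-fold), and Usp12, a deubiquitinase (at least 3.22-fold). The log2 change of Olfr1101 was -4.12 and -2.53 without untransfected arrays 1 and 2. Dll4, Prmt1 and Olfr1101 passed narrowly in limma (adjusted p = 0.0492, 0.0493 and 0.0493). The calls of Dll4, Prmt1, Efnb1, Olfr1101 and Ptgfr were lost whichever siCtrl array was left out.

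In all, 171 probes differed between siCtrl and untransfected cells, 151 higher (98 with 1 gene symbol) and 20 lower (10 with 1 symbol), each by more than 2-fold, with a median absolute log2 change of 2.52. At an unadjusted p under 0.05 there were 1906. The count was 82 without untransfected array 1 (78 higher, 4 lower), 336 without untransfected array 2 (188 higher, 148 lower), and 99, 85 and 92 without siCtrl arrays 1, 2 and 3. Of the 20 named genes, the calls of Zfp750, Ccl5, Slc2a6, Sele and Sdr16c5 held in all 5 of these fits, and 7, 10, 9, 7 and 8 of the 20 calls held in the same order of left-out arrays. With only these 2 groups fitted, limma called 0 probes (1445 at an unadjusted p under 0.05).

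**Figure D2:**
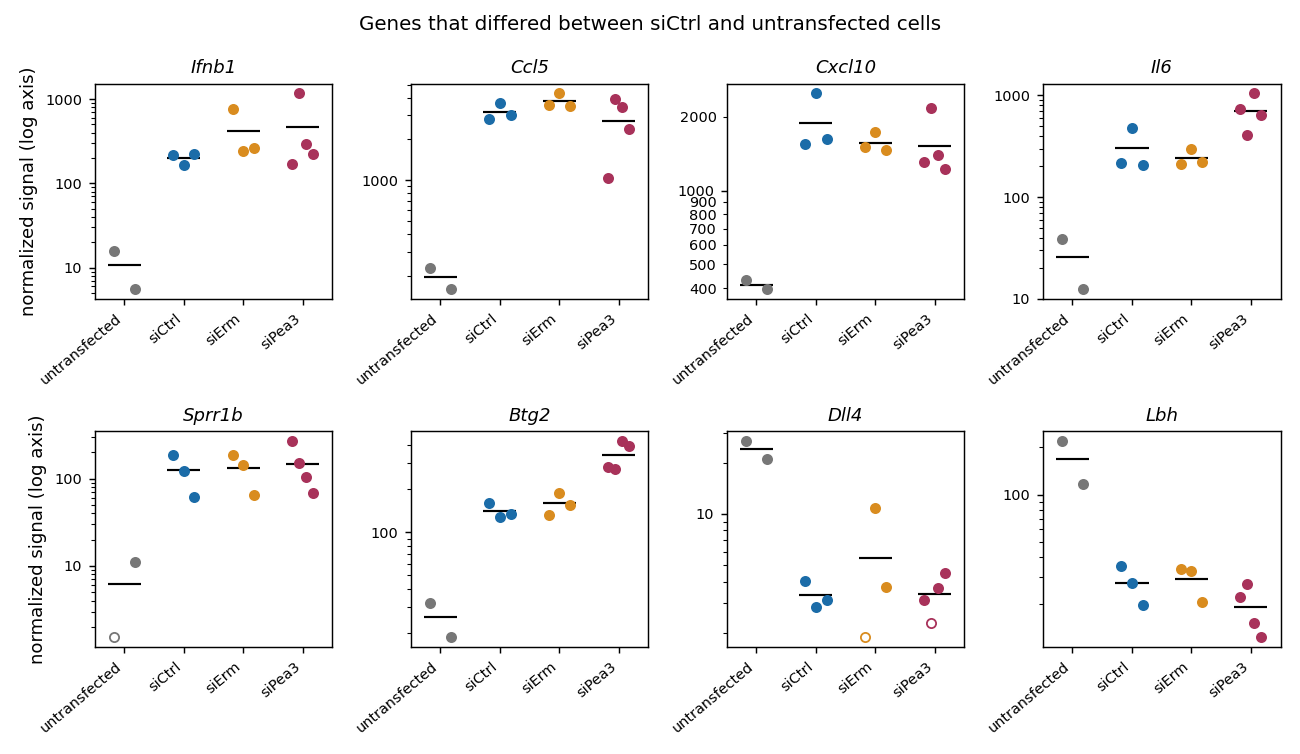
Normalized signal (log axis) on each array, by group, of 8 genes called between siCtrl and untransfected cells; filled points were detected, open points were not, and bars are group means. Ifnb1, Ccl5, Cxcl10, Il6, Sprr1b and Btg2 are lower and Dll4 and Lbh higher in the 2 untransfected arrays than in the 3 siCtrl arrays.

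Interferon response genes rose as a group with transfection. Of 29 measured list genes, 26 had higher estimates, 9 passed over all probes and 22 passed adjusted over the list alone, with a median log2 change of 1.33 (camera adjusted p = 1.54e-20; adjusted p = 0.173 with an estimated correlation; fry adjusted p = 0.000714). Examples were Cxcl10, a chemokine (414 ± 24.2 to 1890 ± 525), Gbp2, a guanylate-binding protein (log2 2.28 ± 0.33), and Igtp, an immunity-related GTPase (log2 1.90 ± 0.24). The calls of Gbp2 (adjusted p = 0.0699) and Cxcl10 (0.0549) were lost without untransfected array 1, in ranges of 0.000403 to 0.162 and 0.00024 to 0.182 over 17 alternatives, and the group's call was kept without any 1 array.

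Inflammatory mediators of the NF-kB list rose as well. Of 16 genes, 3 passed over all probes (Il6, Ccl7 and Csf3) and 8 adjusted over the list alone (relative median 1.15, camera adjusted p = 7.16e-05; adjusted p = 0.876 with an estimated correlation). The relative median was 0.57 without untransfected array 2 and 0.66 with no filter on dim probes. Ccl7, a monocyte chemokine, rose from 147 ± 141 (n = 2) to 911 ± 147 (n = 3), and Csf3, the granulocyte growth factor, from 774 ± 90.7 to 2290 ± 431. The call of Ccl7 held only without untransfected array 1 and that of Csf3 in none of the 5 fits that left out an array, with adjusted p values up to 0.135 and 0.14. Csf2 was 205 ± 19.1 against 40.3 ± 41 and did not pass over all probes (adjusted p = 0.0546), but passed without untransfected array 1 (0.0062, in a range of 0.0062 to 0.343 over 17 alternatives). Without untransfected arrays 1 and 2 in turn, the log2 rise was 4.25 and 1.88 for Ccl7 and 4.17 and 1.56 for Csf2.

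Targets of p53, the tumour suppressor that halts growth after DNA damage, were higher with transfection. Btg2, an antiproliferative gene, rose from 25.6 ± 9.67 (n = 2) to 140 ± 17.1 (n = 3; log2 2.50 ± 0.33, adjusted p = 0.00504), and of 13 list genes 1 passed over all probes and 3 adjusted over the list alone (Btg2, Perp and Cdkn1a; camera adjusted p = 0.00831; adjusted p = 0.876 with an estimated correlation). The list's call was lost without siCtrl array 1 (0.0642) and without untransfected array 2, where the relative median was -0.079 (adjusted p = 0.722, 3.54e-08 to 0.722 over 11 alternatives). The apoptosis list was not called (adjusted p = 0.0601), although Casp1, the inflammasome caspase (88.5 ± 5.49 to 361 ± 118), and Bcl2l11, the death activator Bim (9.18 ± 1.34 to 34.6 ± 7.15), rose over all probes. Both calls were lost without untransfected array 1 (adjusted p = 0.0743 and 0.0543), in ranges of 0.000543 to 0.228 and 0.00274 to 0.214 over 17 alternatives.

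Ribosomal protein genes were slightly lower in transfected cells. Of 56, 48 lay below the median of all probes, 0 passed in the limma fit over all probes or over the list alone (2 at an unadjusted p under 0.05), and the relative median was -0.17 (camera adjusted p = 0.00471; adjusted p = 0.964 with an estimated correlation). The call was lost without siCtrl array 3 (0.0846) and after quantile normalization (0.0607), in a range of 6.8e-05 to 0.139 over 11 alternatives. The other 31 lists had adjusted p values of 0.0601 to 0.927, and the count of called lists, 4, became 10 and 8 without untransfected array 1 and 2.

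The comparison of siPea3 with siCtrl cells asks which genes depend on Pea3. Slc5a1, the intestinal sodium-glucose cotransporter, was at least 6.69-fold higher in siPea3 cells, 4.01 ± 1.31 (n = 4) against an undetected 0.583 ± 0.0961 (n = 3; log2 2.74 ± 0.32, adjusted p = 0.0177). Prl3d2, a placental prolactin family gene whose near-identical copies a probe can also read, was at least 6.63-fold lower, 0.43 ± 0.099 (undetected) against 3.36 ± 0.849 (log2 -2.96 ± 0.36, adjusted p = 0.0177). Cd70, a ligand of the tumour necrosis factor family, was 13.2 ± 6.61 against an undetected 1.03 ± 0.164, at least 11.1-fold, and did not pass (adjusted p = 0.0527). Has2, a hyaluronan synthase, was 3.98 ± 1.69 against 25.6 ± 9.67 (adjusted p = 0.0853) and Dusp9, a phosphatase of MAP kinases, 3.15 ± 1.64 against 16.9 ± 6.49 (adjusted p = 0.084), neither passing.

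In all, 6 probes passed in siPea3 against siCtrl cells, 4 higher and 2 lower, and 2239 (13.4%) had an unadjusted p under 0.05. Of the 4 without a gene symbol, named here after their values were seen, the higher were probes 888990 (149 against 27.1), 712621 (215 against 31.7) and 513911 (25.1 against 8.42). The lower was 644831 (3.59 against 25.2). In untransfected cells their means were 3.88, 1.27, 4.26 and 14 in the same order, so all 4 means were higher in siCtrl than in untransfected cells. Other genes with a small p that did not pass were Hoatz (log2 2.64 ± 0.39, adjusted p = 0.0527), Mmel1 (at least 6.44-fold higher, adjusted p = 0.0654), Aldh1l1 (log2 2.07 ± 0.35, adjusted p = 0.084; another probe for it gave -0.084, adjusted p = 0.97), Prl3d3 (log2 -3.45 ± 0.50, adjusted p = 0.0527) and Slc35g1 (at least 3.51-fold lower, adjusted p = 0.0885). With the replicate block, which treats arrays of 1 number as paired, limma called 0 (1816 at an unadjusted p under 0.05). It also called 0 with only these 2 groups (2121). The count was also 0 without siCtrl array 2 (1405), siCtrl array 3 (2393) or siPea3 array 4 (1727), 2 without siCtrl array 1, and 22, 71, 87 and 35 with quantile normalization, an intensity trend, array weights and scaling over detected probes. Of these, 17, 30, 45 and 31 were higher and 5, 41, 42 and 4 lower. With median scaling over all probes it was 6, of which 5 were shared, 3 higher and 3 lower. It was 9 without siPea3 array 2. Without siPea3 array 2 and siCtrl array 2 together, whose correlations with their own groups were lowest, it was 0 (1313). The call of Slc5a1 was lost without siCtrl arrays 1 (0.0576), 2 (0.0758) and 3 (0.12) and siPea3 array 4 (0.0797), in a range of 0.00477 to 0.183 over 19 alternatives. That of Prl3d2 was lost without siCtrl arrays 1 (0.0524), 2 (0.109) and 3 (0.12) and siPea3 arrays 1 (0.0515), 3 (0.0587) and 4 (0.0571), in a range of 0.0109 to 0.183 over 20. Of the probes without a symbol, 513911 lost its call in all 7 fits that left out 1 array, 712621 in 5, and 644831 and 888990 in 4 each. Over 20 alternatives their log2 changes stayed within 1.44 to 1.91, 2.48 to 3.29, -3.05 to -2.54 and 2.35 to 2.76 in that order. Their adjusted p values ranged over 0.0118 to 0.364, 0.00092 to 0.183, 0.00092 to 0.183 and 0.000764 to 0.183.

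Scaling moved the median of all probes in this comparison. It was -0.24 on the log2 scale as deposited, -0.05 after quantile normalization, -0.29 after median scaling and 0.07 after scaling over detected probes, and between siPea3 and siErm cells it was -0.20, -0.03, -0.20 and 0.06 in the same order. Changes of gene lists are therefore given relative to that median.

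Targets of p53 were higher in siPea3 than in siCtrl cells. Of 13 genes, 13 lay above the median of all probes, and the relative median was 1.12 (camera adjusted p = 2.43e-09; adjusted p = 0.876 with an estimated correlation). None passed over all probes and 3 rose adjusted over the list alone. These were Btg2 (140 ± 17.1, n = 3, to 345 ± 77.3, n = 4), Ei24, an endoplasmic reticulum protein gene induced by p53 (230 ± 31.7 to 500 ± 77.8), and Phlda3, an inhibitor of Akt (573 ± 148 to 1000 ± 110). Bbc3, the death activator Puma, was 309 ± 53.7 against 140 ± 23.6 and did not pass (0.0643 adjusted over the list alone). The list's call held without each single array and with the replicate block (adjusted p = 2.04e-07, 5.12e-10 to 3.51e-06 over 13 alternatives). These alternatives keep the preset correlation, and fry did not call the list (adjusted p = 0.207).

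Genes of lipid synthesis were lower in siPea3 cells. Of 13 measured cholesterol synthesis genes, 12 lay below the median of all probes, with a relative median of -1.09 (camera adjusted p = 0.000186; adjusted p = 0.876 with an estimated correlation), and 0 passed over all probes and 5 adjusted over the list alone. Sqle, squalene epoxidase, fell from 410 ± 146 (n = 3) to 159 ± 28 (n = 4), Msmo1, a sterol oxidase, from 360 ± 135 to 132 ± 28.9, Fdft1, squalene synthase, from 182 ± 80.7 to 52 ± 12.6, and Cyp51, lanosterol demethylase, from 69.7 ± 14 to 24.1 ± 3.76, all adjusted over the list alone. Of 15 genes of fatty acid and lipid synthesis, 13 lay below the median of all probes and 9 fell adjusted over the list alone, 0 over all probes (relative median -0.95, camera adjusted p = 0.00191; adjusted p = 0.876 with an estimated correlation). Fasn, fatty acid synthase, went from 262 ± 24.8 to 104 ± 13.7, and the desaturases Fads1 and Fads2 from 585 ± 181 to 255 ± 64.6 and from 15.1 ± 0.498 to 6.1 ± 1.51. Acsl3, which activates fatty acids, went from 94.4 ± 23.5 to 37.9 ± 3.53. The calls of both lists held without each single array and with the replicate block (adjusted p = 3.77e-05 and 0.00271), in ranges of 3.96e-07 to 0.00311 and 9.81e-06 to 0.0355 over 13 alternatives. These keep the preset correlation, and fry called neither list (adjusted p = 0.267 and 0.119).

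Inflammatory mediators and interferon response genes moved in opposite directions in siPea3 cells. Of 16 genes of the NF-kB list, 15 had higher estimates than in siCtrl cells (relative median 0.71, camera adjusted p = 4.96e-05; adjusted p = 0.876 with an estimated correlation), and 0 passed in limma over all probes or over the list alone. Csf2, the granulocyte-macrophage growth factor, was 673 ± 228 (n = 4) against 205 ± 19.1 (n = 3), Il6 705 ± 264 against 301 ± 154, Cxcl1 6530 ± 242 against 4170 ± 794, and Csf3, the exception, 1200 ± 147 against 2290 ± 431. Of 29 interferon response genes, 21 lay below the median of all probes (relative median -0.23, camera adjusted p = 0.0045; adjusted p = 0.876 with an estimated correlation). Oasl1, an antiviral oligoadenylate synthetase-like gene (174 ± 101 to 38.6 ± 14.6), Ifi204 (450 ± 72.7 to 233 ± 43.3) and Psmb8, an immunoproteasome subunit (568 ± 95.7 to 298 ± 90.7), fell adjusted over the list alone, and 0 passed over all probes. The interferon call was lost without siCtrl array 3 (adjusted p = 0.0557, 8.27e-05 to 0.0557 over 13 alternatives). The relative median was -0.38 without siCtrl array 1, -0.36 without siPea3 array 2 and -0.39 with no filter on dim probes. That of the NF-kB list was 0.44 with no filter. NF-kB genes also lay higher and p53 targets higher in siCtrl than in untransfected cells, as given above.

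Other list calls in siPea3 against siCtrl cells were less firm. Genes of the unfolded protein response were lower (17 genes, relative median -0.49, camera adjusted p = 0.00951; adjusted p = 0.876 with an estimated correlation). Among them Manf (299 ± 40.5, n = 3, to 144 ± 9.08, n = 4) and Creld2 (235 ± 31.8 to 102 ± 27.9), both secretory stress proteins, fell adjusted over the list alone and 0 over all probes. That call was lost without siCtrl array 1 (0.0746), siCtrl array 3 (0.0557) or siPea3 array 2 (0.0619), in a range of 8.27e-05 to 0.0746 over 13 alternatives. DNA replication genes such as Cdc6 (27.6 ± 4.49 against 13.7 ± 2.37 in siPea3 cells) and Mcm6 (216 ± 1.53 against 126 ± 35.2) had a relative median of -0.20 (15 genes, 0 passing over all probes or over the list alone in limma, 4 at an unadjusted p under 0.05; camera adjusted p = 0.0481; adjusted p = 0.922 with an estimated correlation). The call held without siCtrl array 1 (relative median -0.35) and siPea3 array 2 and was lost without siCtrl arrays 2 (0.239, relative median -0.085) and 3 (0.0557) and siPea3 arrays 1 (0.0829), 3 (0.104) and 4 (0.106), with the replicate block (0.115), with quantile normalization (0.409, relative median -0.11), with scaling over detected probes (0.2) and without siPea3 array 2 and siCtrl array 2 together (0.152), in a range of 0.00982 to 0.409 over 13 alternatives. With no filter on dim probes the relative median was -0.35. Basal and myoepithelial markers were called higher (6 genes, 3 above the median of all probes, camera adjusted p = 0.0481; adjusted p = 0.876 with an estimated correlation), through Lamb3, a laminin subunit (1.9 ± 1.21 to 18.9 ± 5.61; log2 3.59, and 2.81 without siCtrl array 2), and Krt17, a keratin (8.88 ± 0.938 to 25 ± 8.05), which rose adjusted over the list alone, with 0 over all probes. This call held only without siCtrl array 1 among the left-out arrays, and was lost without siCtrl arrays 2 (0.125) and 3 (0.0557) and siPea3 arrays 1 (0.0673), 2 (0.055), 3 (0.0706) and 4 (0.0975), with the replicate block (0.146), with quantile normalization (0.151), with scaling over detected probes (0.225) and without siPea3 array 2 and siCtrl array 2 together (0.173). Its relative median was 0.36, and -0.014 with no filter on dim probes, over a range of adjusted p of 0.0353 to 0.693.

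The other 27 lists were not called in siPea3 against siCtrl cells (adjusted p 0.073 to 0.976). Among them, 18 measured genes named in the literature as PEA3 group targets had a relative median of -0.25, with 13 lower estimates (camera adjusted p = 0.822), and limma passed 0 over all probes or over the list alone (1 at an unadjusted p under 0.05). Mmp1a, an interstitial collagenase, was 0.852 ± 0.39 (n = 4) against 2.82 ± 0.946 (n = 3; adjusted p = 0.277), Snai1, an inducer of epithelial-mesenchymal transition, 6.89 ± 5.63 against 12.4 ± 4.91 (adjusted p = 0.43), Erbb2 8.51 ± 2.9 against 12.2 ± 2.67 (adjusted p = 0.423) and Vim, vimentin, 3880 ± 755 against 5540 ± 1060 (adjusted p = 0.379). Ribosomal protein genes had a relative median of 0.012 (camera adjusted p = 0.41, on the lower side), and were called lower without siPea3 array 2 (0.00302, in a range of 0.00302 to 0.92 over 13 alternatives). The count of called lists, 8, became 4 without siCtrl array 3 and stayed at 8 without siPea3 array 2 and siCtrl array 2, of which 6 were shared.

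**Figure D3:**
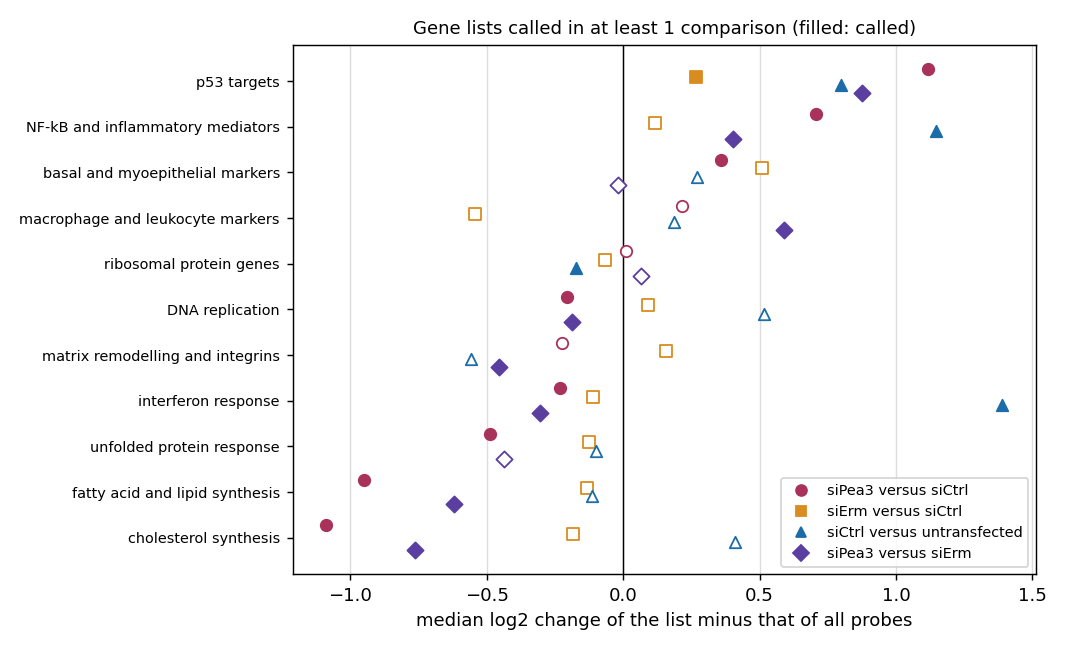
Median log2 change of each gene list minus that of all probes, in the 4 comparisons, for the 11 lists called in at least 1; filled marks were called by camera with the preset correlation, open marks were not. Cholesterol synthesis lies at -1.09 and p53 targets at 1.12 in siPea3 against siCtrl cells, and interferon response at 1.39 in siCtrl against untransfected cells.

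The comparison of siErm with siCtrl cells asks which genes depend on Erm. No probe passed in limma (0 of 16724, smallest adjusted p 0.902), and 339 (2.03%) had an unadjusted p under 0.05. The genes with the smallest p did not pass. On the higher side these were Mmp20, enamelysin (at least 4.85-fold), Myo1c, a myosin (at least 4.1-fold), B4galt6, a galactosyltransferase (at least 2.97-fold), Bmp4, a bone morphogenetic protein (at least 2.62-fold), and Fbxo36 (7.21 ± 1.36 against 3.07 ± 1.04, n = 3 and 3). On the lower side they were Hgf, hepatocyte growth factor (0.997 ± 0.293 against 3.07 ± 0.76), Zfp128 (at least 2.55-fold), Skor1 (at least 2.63-fold), 4930555G01Rik (at least 3.87-fold) and Cndp1 (at least 2.08-fold). These signals lie near background. The log2 change of Mmp20 was 2.95 and 1.72 without siErm arrays 1 and 3, and that of 4930555G01Rik -2.60 and -1.27 without siCtrl arrays 1 and 2. The count was 0 in every alternative tried. At an unadjusted p under 0.05 there were 385 with the replicate block, 859 with the block within only these 2 groups, and 294 to 467 with 1 array left out. The main fit does not use the pairing by number that these arrays appear to have, which can hide changes. A count of 0 therefore does not show that no gene changed.

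Among the lists, p53 targets were higher in siErm than in siCtrl cells, with 11 of 13 estimates above the median of all probes and a relative median of 0.27 (camera adjusted p = 0.0182; adjusted p = 0.895 with an estimated correlation). Limma passed 0 of them over all probes and 0 adjusted over the list alone (0 at an unadjusted p under 0.05). Ei24 was 311 ± 13.3 (n = 3) against 230 ± 31.7 (n = 3) and Sesn2, a stress-induced sestrin, 83.4 ± 21.4 against 55.5 ± 29.7. The call was lost without siCtrl array 2 (0.439, relative median 0.078), siCtrl array 3 (0.0557), siErm array 2 (0.116) or siErm array 3 (0.0601), with no filter on dim probes (0.137) and without siPea3 array 2 and siCtrl array 2 together (0.378), in a range of 0.00553 to 0.439 over 12 alternatives. The other 34 lists were not called (adjusted p 0.0787 to 0.998), the lowest p being that of the literature targets of the PEA3 group (relative median 0.26; adjusted p = 0.876 with an estimated correlation). The count of called lists, 1, became 4 without siCtrl array 1, 0 without siCtrl array 3 and 2 without siErm array 3.

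The knockdowns shared no called probe against siCtrl, since limma called 0 in siErm cells (339 at an unadjusted p under 0.05). At an unadjusted p under 0.01, 7 probes were higher in both and 11 lower in both, where 0.389 and 0.773 would be met by chance if the comparisons were independent, and 1 went opposite ways. Both comparisons use the same 3 siCtrl arrays, which makes their changes correlate. Across 16724 probes, which are not independent replicates, the log2 changes correlated at r = 0.44 (covariance 0.113), against 0.511 to 0.554 (covariance 0.139 to 0.156) in 100 simulations of unchanged groups with shared controls. The simulations leave out any pairing of arrays by number, which can lower these values. No conclusion was drawn from the difference. The 3 siCtrl arrays cannot be split into separate controls of at least 2 arrays, so a shared response was not separated from the shared controls.

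The direct comparison of siPea3 with siErm cells tests whether the knockdowns differ. Probe 888990, without a gene symbol and named after its values were seen, was 149 ± 27.4 (n = 4) in siPea3 and 25 ± 5.22 (n = 3) in siErm cells (log2 2.58 ± 0.26, adjusted p = 0.0131), and it was the 1 probe called (1722 at an unadjusted p under 0.05). Its mean was 3.88 in untransfected and 27.1 in siCtrl cells. Cd70 was at least 12.8-fold higher and Slc5a1 at least 4.73-fold higher in siPea3 cells (adjusted p = 0.0558 for both), and Cbs, the enzyme that makes cystathionine, was 29 ± 2.7 against 9.22 ± 2.92 (adjusted p = 0.0884), none passing. Prss2, a trypsinogen (at least 6.41-fold higher, adjusted p = 0.113), and Nlrp5 (at least 2.9-fold higher, adjusted p = 0.135) did not pass. On the lower side, Dusp9 (3.15 ± 1.64 against 18.5 ± 5.36), P2ry12, an ADP receptor (2.05 ± 0.821 against 12.5 ± 5.87), Wdfy1 (6.4 ± 1.52 against 18.8 ± 0.941), Fbxo36 (2.17 ± 0.377 against 7.21 ± 1.36) and Prl3d2 (at least 4.07-fold) had an adjusted p of 0.0884 and did not pass. The count was 2 without siErm array 1 or siPea3 array 1 and 0 without siErm array 2 (933), siErm array 3 (1703), siPea3 array 2 (1368), siPea3 array 3 (1488) or siPea3 array 4 (1457), with counts at an unadjusted p under 0.05 in brackets.

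Of the 8 lists called between these knockdowns, 6 were also called in siPea3 against siCtrl cells. Both comparisons use the same 4 siPea3 arrays, so their calls are not independent. Against siCtrl cells, matrix remodelling (camera adjusted p = 0.413) and macrophage markers (0.511) were not called. Here the unfolded protein response (0.073) and basal markers (0.307) were not. Targets of p53 were higher in siPea3 cells (relative median 0.88, camera adjusted p = 1.27e-05; adjusted p = 0.876 with an estimated correlation), with Btg2, 345 ± 77.3 (n = 4) against 158 ± 27.9 (n = 3), passing adjusted over the list alone and 0 over all probes. Cholesterol synthesis genes were lower (relative median -0.76, camera adjusted p = 0.00171; adjusted p = 0.922 with an estimated correlation), as were those of fatty acid and lipid synthesis (relative median -0.62, camera adjusted p = 0.00411; adjusted p = 0.876 with an estimated correlation). Of these, Fasn fell adjusted over the list alone, 238 ± 28 to 104 ± 13.7, with 0 over all probes, and Cyp51 was 24.1 ± 3.76 against 74.1 ± 29.9 without passing. Interferon response genes were lower (29 genes, relative median -0.30, camera adjusted p = 0.00618; adjusted p = 0.876 with an estimated correlation) and NF-kB genes higher (16 genes, relative median 0.40, camera adjusted p = 0.00285; adjusted p = 0.876 with an estimated correlation), with 0 members passing in limma over all probes or over the list alone. Il6 was 705 ± 264 in siPea3 and 243 ± 48.3 in siErm cells. The NF-kB call was lost without siErm array 2 (adjusted p = 0.0631, 0.000939 to 0.0631 over 13 alternatives) and with no filter on dim probes (0.0501, relative median 0.26). The relative median of the interferon list was -0.19 without siErm array 2.

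DNA replication genes were lower in siPea3 than in siErm cells (15 genes, relative median -0.19, camera adjusted p = 0.00831; adjusted p = 0.876 with an estimated correlation). Cdc6, 29.1 ± 2.74 (n = 3) to 13.7 ± 2.37 (n = 4), and Mcm6, 261 ± 56 to 126 ± 35.2, fell adjusted over the list alone, with 0 over all probes. The call was lost without siErm array 1 (0.0519, relative median -0.28) and after quantile normalization (0.0607), in a range of 0.00341 to 0.0607 over 13 alternatives. With no filter on dim probes the relative median was -0.28. Genes of matrix remodelling and integrins were lower (25 genes, relative median -0.45, camera adjusted p = 0.0481; adjusted p = 0.922 with an estimated correlation), for example Tnc, the matrix protein tenascin C, 221 ± 71.1 against 552 ± 194. That call was lost without siErm array 1 (0.367, relative median -0.24) and siPea3 arrays 1 (0.0571), 2 (0.216) and 4 (0.0516), and without siPea3 array 2 and siCtrl array 2 together (0.275), in a range of 0.00405 to 0.367. Macrophage and leukocyte markers were called higher on 4 genes (relative median 0.59, camera adjusted p = 0.0391; adjusted p = 0.876 with an estimated correlation). Their signals were low or alike, with Cd52 at 1.51 ± 0.481 against an undetected 0.447, Lyz2 at 6.28 ± 0.75 against 4.73 ± 1.97, and Cd14 at 43.3 ± 14.8 against 37.7 ± 7.08. The call was lost without siErm arrays 1 (0.0896) and 3 (0.0689) and siPea3 arrays 1 (0.0727), 2 (0.055) and 4 (0.095), and with no filter on dim probes (0.171), in a range of 0.01 to 0.171. No member of the matrix or macrophage lists passed in limma over all probes or over the list alone. The other 27 lists had adjusted p values of 0.073 to 0.995, and the count of called lists, 8, became 5 without siErm array 1.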

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

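Of the tests below, those on white blood cells and on the response to transfection were chosen after the results they weigh were seen. Differences between the effects of the 2 siRNAs, tested directly as siPea3 against siErm, singled out 1 probe and 8 gene lists. With an estimated correlation, camera called none of these lists (adjusted p 0.876 to 0.922). Probe 888990, without a gene symbol, had a log2 difference of 2.58. Relative to all probes, the list medians differed by 0.88 for p53 targets, 0.40 for NF-kB and inflammatory mediators, 0.59 for macrophage and leukocyte markers, -0.76 for cholesterol synthesis, -0.62 for fatty acid and lipid synthesis, -0.30 for interferon response, -0.19 for DNA replication and -0.45 for matrix remodelling and integrins. A gap test for single arrays, possible only in the siPea3 group, singled out none (0 of 24 measures), although siPea3 array 2 had 11286 detected probes against 13293 to 13814 on the other siPea3 arrays.

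Interferon response genes were higher in siCtrl than in untransfected cells, by a relative median of 1.39. White blood cells in the siCtrl cultures would raise leukocyte markers. Of 13 such markers, the 4 tested had a relative median of 0.19, with an SD between genes of 0.365. These showed no rise like that of the interferon list, but so few markers cannot exclude that source on their own. Both groups are cultures of the same cell line, so the design gives no source of white blood cells. A single array setting the difference is argued against, since the lowest relative median without 1 array was 1.00 (without untransfected array 1). The groups differ in having been transfected, so the values are consistent with a response to transfection (relative median of at least 1.00 without any 1 array), although the siRNA and the reagent cannot be told apart in this design.

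Targets of p53 were higher and genes of cholesterol and fatty acid synthesis lower in siPea3 than in siCtrl cells. The weak signals of siPea3 array 2 are argued against as the source, since each relative median kept at least 102% of its size without that array. A stronger response to transfection in the siPea3 cells stayed open for the p53 part. The 151 probes higher in siCtrl than in untransfected cells had a relative median of 0.15 in siPea3 against siErm cells. Its 95% bootstrap interval, 0.0194 to 0.29, resampled probes and does not measure the spread between cultures. Interferon response genes, which rose with transfection by 1.39, had a relative median of -0.30 in siPea3 against siErm cells (-0.19 without siErm array 2). For the lipid part a stronger response also stayed open. As a set the 28 lipid synthesis genes were not lower in siCtrl than in untransfected cells (relative median 0.020, SD between genes 0.723, 14 above 0). In siPea3 against siCtrl cells their relative median was -1.02. The cholesterol list alone was at 0.41 in siCtrl against untransfected cells. Both comparisons use the same 3 siCtrl arrays with opposite signs. In siPea3 against siErm cells, which leaves those arrays out, the cholesterol and fatty acid lists were still lower (-0.76 and -0.62). In siErm against siCtrl cells they were at -0.18 and -0.13. No fall with transfection was seen. That value rests on 2 untransfected arrays, and the SD does not measure the spread between arrays, so the test cannot tell. Loss of Pea3 and an effect of this siRNA on other transcripts were not told apart, and the calls were lost with an estimated correlation (adjusted p = 0.876).

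Other splits of the arrays tell whether chance can be excluded. For siPea3 against siCtrl, 1 of 35 splits, the real one, gave as many called probes (6, highest other 1). Pairing by replicate number is uncertain for these arrays. The 8 splits that part as many pairs are too few for a share under 0.05 (6, highest other 0). For the list count a chance split is not excluded, since 2 of 35 splits gave as many (8, highest other 8), and the 8 that part as many pairs are again too few (8, highest other 5). For siPea3 against siErm, 1 of 35 splits gave as many probes (1, highest other 0), which says only that a single probe passed, and 2 of 35 gave as many lists (8, highest other 8), so chance is not excluded for the lists. For siErm against siCtrl the 10 splits are too few: 10 of 10 gave as many probes (0, highest other 0) and 9 of 10 as many lists (1, highest other 4).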

How the results depend on the processing

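Signs held more often than calls. All 6 probes called in siPea3 against siCtrl cells and all 171 called in siCtrl against untransfected cells kept their sign in every alternative that tested them, of which the stricter filter tested 5 and 155. Signals near background limit what could be seen: 34.2% to 41.9% of probes were detected per array, and the Etv5 probe was not detected on any siErm or siPea3 array. Where a left-out array leaves 1 untransfected array, that array is assumed to vary like the other groups. In siCtrl against untransfected cells, where pairing by number is not settled, the replicate block kept the calls of 9 of the 20 named genes. It ended those of Casp1, Bcl2l11, Il6, Ccl7, Csf3 and Psmb10. It also ended those of the p53 (camera adjusted p = 0.0879) and ribosomal lists (0.139). In siPea3 against siErm cells it ended the call of the macrophage markers (0.0689, 0.01 to 0.171). Apart from these and the calls given below or beside the result, the replicate block changed no other call of a named gene or a list.

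The number of probes called in siPea3 against siCtrl cells, 6, was 22 with quantile normalization, 71 with an intensity trend, 87 with array weights and 35 with scaling over detected probes. It was 0 with only the groups compared (2121 at an unadjusted p under 0.05), 0 with the replicate block (1816), 0 with both (1646) and 0 without the 2 arrays farthest from their groups (1313), and 0 to 9 without 1 array. In siCtrl against untransfected cells, 171 became 289 with quantile normalization, 110 without the filter, 262 with an intensity trend, 0 with only the groups compared (1445), 100 with the block, 83 with array weights, 272 with scaling over detected probes, 92 without the 2 arrays, and 82 to 336 without 1 array. In siPea3 against siErm cells, 1 became 13 with quantile normalization, 4 with the stricter filter, 9 with an intensity trend, 69 with array weights, 5 with scaling over detected probes, 0 with only the groups compared (1755), 0 with the block (1649), 0 without the 2 arrays (1572) and 0 to 2 without 1 array. In siErm against siCtrl cells it was 0 throughout (109 to 1059). Fits of fewer arrays have fewer degrees of freedom, and otherwise the cause was not tested.

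The number of called lists fell to 0 with an estimated correlation in all 4 comparisons. With fry it was 0, 0, 1 and 0 in siPea3 against siCtrl, siErm against siCtrl, siCtrl against untransfected and siPea3 against siErm cells. It was 0 without the filter and 2 without the 2 arrays in siErm against siCtrl cells, and 2 with the block in siCtrl against untransfected cells. Without 1 array it was 4 to 8, 0 to 4, 3 to 10 and 5 to 9 in the same order. The shared response of the knockdowns, 0 probes, was 18 at an unadjusted p under 0.01.

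Some estimates turned, and the cause was not tested. Etv4 in siErm against siCtrl cells was 0.016 without the 2 arrays and -0.32 to 0.072 without 1 array. In siCtrl against untransfected cells Etv1 was -0.15 without the 2 arrays and -0.15 to 0.45 without 1, and Etv5 -4.01 to 0.49 without 1. In siPea3 against siErm cells Etv5 was 0.11 with scaling over detected probes and -0.47 to 0.43 without 1 array, Laptm5 was -0.23 with the block and -0.23 to 0.67 without 1 array, and Cd14 -0.050 to 0.31 without 1. For ribosomal protein genes the direction of the camera test turned. Their relative median, given here, did not always change sign with it. In siPea3 against siCtrl cells this median was 0.10 with the block, 0.012 with scaling over detected probes and -0.16 to 0.10 without 1 array. In siErm against siCtrl cells it was 0.011 with quantile normalization, -0.025 without the 2 arrays and -0.10 to -0.025 without 1. In siPea3 against siErm cells it was 0.17 with the block, 0.065 with scaling over detected probes and -0.10 to 0.17 without 1.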

Other observations

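The lists and genes of this part were chosen after the values of the comparisons were seen. Guanylate-binding proteins and immunity-related GTPases, which act against pathogens inside cells, rose with transfection. Of 7 measured genes, 7 lay above the median of all probes in siCtrl against untransfected cells, and Tgtp1 (log2 2.95 ± 0.33, n = 3 and 2, adjusted p = 0.00188) and Gbp8 (log2 2.39 ± 0.27, adjusted p = 0.00198) rose over all probes. The relative median was 1.25 (camera adjusted p = 5.44e-09; adjusted p = 0.105 with an estimated correlation). Genes of antigen presentation by MHC class I also rose, with a relative median of 0.86 over 12 genes (camera adjusted p = 4.51e-06; adjusted p = 0.105 with an estimated correlation). Tapbpl, a peptide editor related to tapasin, rose by 2.55 ± 0.28 (adjusted p = 0.00165), and Psmb10, an immunoproteasome subunit, by 1.69 ± 0.35 (adjusted p = 0.0495). The rise of Psmb10 was 1.06 and 2.31 without untransfected arrays 1 and 2, and its call was lost without untransfected array 1 (0.264) and siCtrl arrays 1 (0.099), 2 (0.162) and 3 (0.113), in a range of 0.00598 to 0.412 over 17 alternatives.

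Keratinocyte differentiation genes were tested as a group because Sprr1b, Ivl and Zfp750 were among the largest rises. Their relative median was 0.55 over 21 genes in siCtrl against untransfected cells (camera adjusted p = 0.00883, and 0.105 with an estimated correlation). The bootstrap interval, which resampled genes and not cultures, was 0.146 to 0.736. The call was lost without untransfected array 1 (0.07, relative median 0.24) and with no filter on dim probes (0.0872, relative median 0.22), in a range of 0.00699 to 0.0872 over 11 alternatives. The relative median was 0.86 without untransfected array 2. Krt16, a keratin of stressed epidermis, rose by 2.95 ± 0.52 on the log2 scale (adjusted p = 0.0252). Its call was lost without untransfected array 1 (0.179) and siCtrl arrays 1 (0.0527), 2 (0.0947) and 3 (0.0796), in a range of 0.00308 to 0.179 over 17 alternatives. The group was also called higher in siPea3 against siCtrl cells (relative median 0.38, camera adjusted p = 0.00883; adjusted p = 0.105 with an estimated correlation) and in siErm against siCtrl cells (relative median 0.15, camera adjusted p = 0.0342; adjusted p = 0.17 with an estimated correlation), and was not called in siPea3 against siErm cells (camera adjusted p = 0.435). The siPea3 call was lost without siCtrl array 3 (0.0535) and with quantile normalization (0.0885), in a range of 0.00343 to 0.0885 over 13 alternatives. The siErm call was lost without siCtrl arrays 1 (0.0731) and 3 (0.282) and siErm arrays 2 (0.0983) and 3 (0.205), with the replicate block (0.0761), quantile normalization (0.0885), scaling over detected probes (0.0914) and no filter on dim probes (0.0872), in a range of 0.0164 to 0.282 over 12. Its relative median was 0.36 without siCtrl array 1 and 0.084 without siErm array 1.

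Lower cholesterol synthesis with sterol excess would come with higher LXR targets, genes that sterols induce. The 10 LXR targets measured had a relative median of -0.31 in siPea3 against siCtrl cells (camera adjusted p = 0.296). Of these, 2 of 10 lay above the median of all probes. The bootstrap interval, which resampled genes and not cultures, was -0.613 to 0.231. On balance these targets moved lower by fry, which does not compare them with other genes (adjusted p = 0.0302). No rise was seen, but the interval reaches above 0, so this test cannot tell.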
